A study of Homo sapiens with 9 samples.

How the data were processed

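Messenger RNA of 9 libraries was analysed: 3 of undifferentiated iPSC, 3 of adherent and 3 of bioreactor cultures differentiated toward beta cells. Per the labels' protocols, libraries were made with Illumina Stranded mRNA Prep. Per the submitters' processing notes, the authors trimmed reads with Trim Galore 0.6.7 and aligned them to GRCh38 with STAR 2.6.1, and the deposited table holds raw counts per gene. The counting tool, its strand setting, the annotation release and any filter on the reads are not given in the sources used here. The table had 19977 genes and 9 columns, all of them used, with totals from 15268937 to 18402588 counts. Gene identifiers were matched to GENCODE 29, which held 19860 of them; 117 were not matched and kept their own names, and 1315 genes had 0 counts in every library.

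Counts were scaled with the trimmed mean of M values (TMM) and filtered with filterByExpr at its defaults in edgeR 4.0.16 under R 4.3.3, which left 15757 genes. A model with a mean for each of the 3 groups was fitted to all 9 libraries with edgeR's robust quasi-likelihood method. The 3 comparisons were bioreactor with adherent, adherent with iPSC and bioreactor with iPSC, each with a Benjamini-Hochberg threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. A gene with 0 counts in a whole group was given a floor of 3 counts over the group, and ratios over 1 to 3 counts carry a 95% counting interval. The spread between libraries of a group corresponded to a biological coefficient of variation of 4.35%.

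The 41 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation of 0.01 between genes, for lists with at least 5 tested members. The same lists were tested with camera and an estimated correlation and with fry. The named genes followed a rule: the 8 largest rises and 8 largest falls of each comparison among called genes with at least 20 CPM in the higher group and libraries that did not overlap, without uncharacterised or non-coding genes. To these came 24 genes fixed by name and up to 4 members of each list with the smallest adjusted p. The groups, comparisons, lists, naming rule and alternatives were chosen before the data were examined.

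Alternatives were RLE size factors, upper-quartile factors and library totals as scaling, no filter, at least 10 counts in every library of a group, DESeq2 1.42.0, limma voom, only the 6 libraries compared, a replicate block, an adjusted p of 0.01, a test against 1.5-fold with glmTreat, and leaving out each library in turn. The change shared by both platforms was compared with 20 simulated sets of unchanged groups. The pipeline was tested on simulated data for bioreactor against adherent, with 50 changed genes per fold among 15506. It recovered 84% of them at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 50% at a smaller fold. False calls were 8.38% of all calls, and a comparison without change gave 3 calls. In simulated lists, the shifted list was called by camera with either correlation and by fry, and 0 of 40 unshifted lists were. Genes were simulated independently of each other and few were changed. These simulations therefore do not test lists of correlated genes, or the scaling where most genes change. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out. Raw reads were not used here, and some genes that the naming rule picks are not reported here.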

Results

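Messenger RNA was sequenced from NCRM-1 cells, a human induced pluripotent stem cell (iPSC) line, in 9 libraries that form 3 groups of 3. The iPSC group held undifferentiated cells. The adherent group was differentiated toward pancreatic beta cells while attached to a surface. The bioreactor group was taken toward beta cells in suspension, in a stirred vertical-wheel bioreactor. Whether stage, medium and harvest day matched is not known. Library totals ran from 15268937 to 18402588 counts, and 15757 genes had enough counts to be tested. Levels are given as CPM (counts per library total, scaled by the trimmed mean of M values to a common library size) as mean ± SD over the 3 libraries of a group (n = 3). Log2 fold changes are positive where the group named first was higher, with a standard error (SE) from the test statistic, and a lone number in parentheses after a gene is that gene's log2 fold change, as is the median of a list. The p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether replicates were separate cultures.

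Mitochondrially encoded genes took 6.93% ± 0.375 (SD, n = 3) of the counts in iPSC, 3.30% ± 0.223 in adherent and 2.79% ± 0.185 in bioreactor libraries. Ribosomal protein genes took 6.03% ± 0.269, 4.78% ± 0.196 and 2.04% ± 0.0266 in the same order. Libraries of a group lay close together: the mean chi-square per gene was 2.16 to 4.47 for pairs within a group and 272 to 579 for pairs from different groups. The titles of the bioreactor libraries name another experiment than those of the other groups, so platform and experiment cannot be told apart in the comparisons that use them. The labels also mention a bioreactor treated with PEG and heparin without saying which vessel these libraries came from.

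Comparing bioreactor with adherent libraries bears on the study's question, how platform affects differentiation, though stage may differ too. Islet hormone genes were higher in the bioreactor libraries. GCG, which encodes glucagon, the hormone of alpha cells, stood at 1475 ± 34.4 against 33.8 ± 2.45 CPM (SD, n = 3), and INS, which encodes insulin, at 122 ± 16.4 against 21.6 ± 2.03 CPM. SST, the somatostatin gene of delta cells, stood at 124 ± 1.55 against 14.5 ± 1.1 CPM, and CHGA, a protein of hormone granules, at 2562 ± 152 against 513 ± 14.3 CPM. Epithelial and dividing-cell genes were lower, with the duct keratin gene KRT19 at 5.86 ± 0.716 against 862 ± 31.4 CPM and the proliferation marker MKI67 at 4.78 ± 1.14 against 177 ± 10.3 CPM.

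By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave every gene's adjusted p, GCG (ENSG00000115263) had a log2 fold change of 5.45 ± 0.132 (SE, edgeR adjusted p = 7.82e-10) and INS (ENSG00000254647) of 2.50 ± 0.127 (edgeR adjusted p = 6.21e-08). In GENCODE 29 on GRCh38, GCG lies on chromosome 2, 162142873 to 162152404, minus strand, and INS on chromosome 11, 2159779 to 2161341, minus strand. IAPP, which encodes the amylin that beta cells release with insulin, rose to 7.73 ± 0.419 against 0.0746 ± 0.0302 CPM. The beta cell regulator NKX6-1 (ENSG00000163623, chromosome 4, 84491987 to 84498450, minus strand) rose to 129.9 ± 6.63 against 43.8 ± 2.73 CPM (log2 fold change 1.57, edgeR adjusted p = 4.23e-22). PDX1 (ENSG00000139515, chromosome 13, 27920020 to 27926231, plus strand), a regulator of the pancreas and of the insulin gene, went the other way and fell to 3.23 ± 0.139 against 9.3 ± 0.404 CPM (log2 fold change -1.53, edgeR adjusted p = 1.69e-10). TPH1, the enzyme that starts serotonin synthesis, rose to 59.3 ± 2.56 against 3.26 ± 0.272 CPM. NEUROD1 (2.04), NKX2-2 (1.23), MAFA (3.63) and the endocrine progenitor factor NEUROG3 (1.29) also rose, each given as log2 fold change. SOX9, a progenitor and duct factor, fell (-0.82), as did SOX2 (-1.08), the collagen gene COL1A1 (-5.31) and the liver genes ALB (-2.78) and AFP (-10.18).

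**Figure D1:**
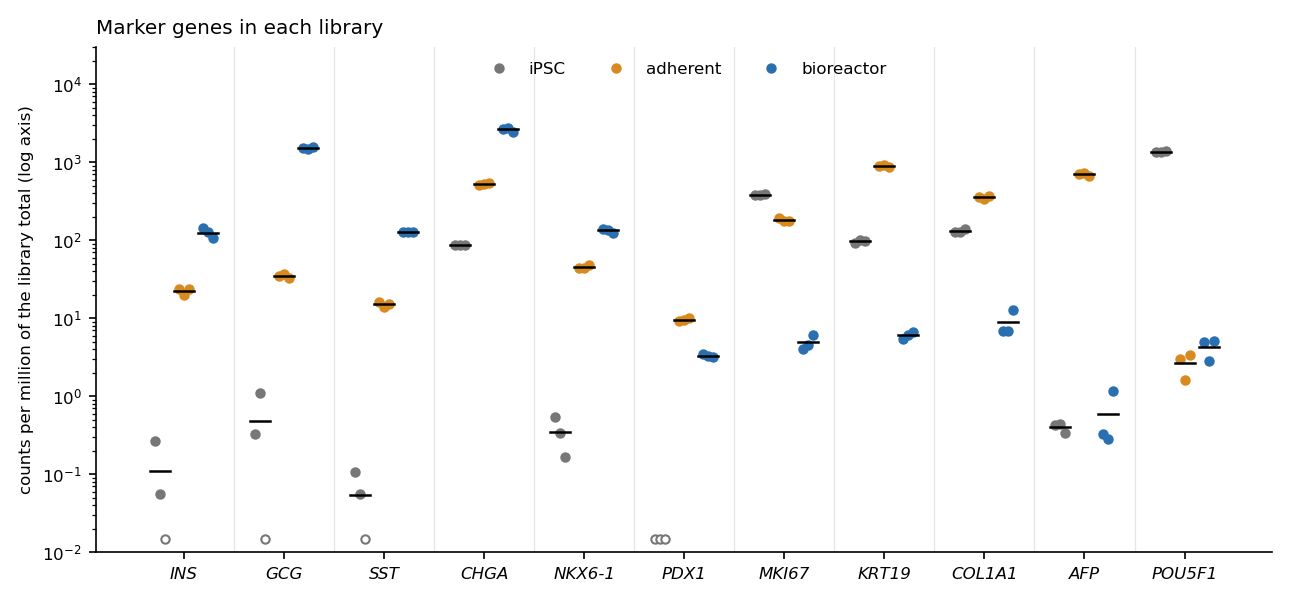
CPM of the library total on a log axis for 11 marker genes in each of the 9 libraries, with iPSC in grey, adherent in orange and bioreactor in blue; black lines are group means and open circles are libraries with 0 counts. GCG and CHGA stand highest in the bioreactor libraries, while KRT19, COL1A1, AFP and MKI67 stand far lower there than in the adherent libraries.

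The 8 genes with the largest rise in the bioreactor libraries were led by HOXB5 (ENSG00000120075, chromosome 17, 48591257 to 48593961, minus strand), a homeobox gene that patterns the body axis, at 324 ± 20.3 against 1.36 ± 0.321 CPM (log2 fold change 7.88). Several of the others belong to neurons: GRIN2B, a subunit of NMDA glutamate receptors (372 ± 26.3 against 2.1 ± 0.223 CPM), GSG1L, an accessory subunit of AMPA receptors (27.1 ± 2 CPM in the bioreactor), and RPH3A, a synaptic vesicle protein (91.9 ± 3.86 CPM). EVX2, a homeobox gene of spinal interneurons (24.5 ± 1.76 CPM), the galanin receptor GALR2 (48.3 ± 3.89 CPM), DTHD1 (68.5 ± 2.99 CPM) and GC, a vitamin D carrier also made by alpha cells (30.3 ± 2.26 CPM), completed the 8; their log2 fold changes ran from 7.28 to 7.61. The epithelial gene ITGB6 (at least 444-fold lower) and the TEAD cofactor VGLL1 (at least 375-fold) had 0 counts in all bioreactor libraries, against a floor of 3 counts over the group. The growth factor AREG was lower by a ratio of 3490 (95% counting interval 1190 to 16900), the membrane protein gene TM4SF1 by 3140 (95% counting interval 1070 to 15200) and the natriuretic peptide gene NPPB by 2340 (95% counting interval 419 to 92300). ANKRD1, a target of the mechanosensitive regulator YAP, stood at 0.198 ± 0.0242 against 462 ± 40 CPM, and FGB, a fibrinogen chain made in the liver, at 0.458 ± 0.0378 against 715 ± 53.8 CPM. These intervals and floors cover counting error only.

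Lists of genes fixed beforehand were tested as groups with camera, and in this comparison rose and fell mean higher and lower in the bioreactor. Among hormone granules and exocytosis, 24 of 26 tested members rose and 2 fell (median log2 fold change 2.78, limma's camera adjusted p = 2.14e-07, adjusted p = 0.0491 with an estimated correlation). Examples were CHGB (399 ± 14.9 against 18.8 ± 1.35 CPM), SNAP25 (4.02) and UNC13A (3.98), all parts of regulated secretion. Of islet ion channels, 19 of 22 tested members rose and 3 fell (median log2 fold change 2.55, limma's camera adjusted p = 0.000291, adjusted p = 0.171 with an estimated correlation). The calcium channel subunits CACNA2D2 (224 ± 8.7 against 31.1 ± 1.8 CPM) and CACNA2D1 and the sodium channel subunit SCN3B rose, while the calcium release channel ITPR3 fell (3.94 ± 0.0586 against 133 ± 6.49 CPM). For insulin production and glucose sensing, 17 of 25 tested members rose, 5 fell and 3 did not pass (median log2 fold change 1.91, limma's camera adjusted p = 0.0189, adjusted p = 0.0884 with an estimated correlation). There were rises in PCSK2, a hormone-cleaving protease (149 ± 6.25 against 10.6 ± 0.454 CPM), SYT13 (2.80), the KATP channel subunit ABCC8 (62.2 ± 3.56 against 3.24 ± 0.607 CPM) and the zinc transporter SLC30A8 (22.5 ± 1.32 against 0.339 ± 0.06 CPM). Neuron markers moved with these 3 lists: 18 of 23 tested members rose and 5 fell (median log2 fold change 2.59, limma's camera adjusted p = 0.000777, adjusted p = 0.253 with an estimated correlation). Examples were MAP2 at 1714 ± 77.3 against 138 ± 2.9 CPM, GAP43 at 551 ± 9.97 against 63.3 ± 1.85 CPM and RBFOX3 at 81.7 ± 3.32 against 1.99 ± 0.275 CPM.

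Other endocrine lists moved both ways and were not called as groups. Of the beta cell transcription factors, 10 of 20 tested members rose, 7 fell and 3 did not pass (median log2 fold change 0.83, limma's camera adjusted p = 0.103); MYT1 (2.35), NKX6-1 and MAFA were among the rises. For alpha cell markers, 9 of 15 tested members rose, 5 fell and 1 did not pass (median log2 fold change 1.21, limma's camera adjusted p = 0.455); GC rose, while the peptidase DPP4 (2.79 ± 0.319 against 81.4 ± 3.19 CPM) and PLCE1 (-3.44) fell. Of the enterochromaffin-like cell markers, which mark serotonin-making cells of such cultures, 8 of 12 tested members rose, 3 fell and 1 did not pass (median log2 fold change 1.03, limma's camera adjusted p = 0.121). An example was TAC1, a tachykinin precursor, at 212 ± 8.73 against 2 ± 0.42 CPM. For delta, gamma and epsilon cell markers, 4 of 10 tested members rose and 6 fell (median log2 fold change -0.91, limma's camera adjusted p = 0.582); SST rose, and SEMA3E, RBP4 and LEPR fell. Among endocrine progenitor genes, 8 of 16 tested members rose, 7 fell and 1 did not pass (median log2 fold change 0.34, limma's camera adjusted p = 0.772). There was a rise in ACVR1C (3.98) and falls in GADD45A, the NOTCH ligand DLL1 (-2.46) and AMOTL2. Adjusted over the list alone, the counts of every list of this comparison were the same, except that 9 endocrine progenitor genes rose.

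HOX genes, which set position along the body axis, were higher in the bioreactor: 17 of 21 tested members rose, 1 fell and 3 did not pass (median log2 fold change 2.39, limma's camera adjusted p = 0.00207, adjusted p = 0.223 with an estimated correlation). HOXD4 (44.3 ± 2.4 against 2.06 ± 0.158 CPM), HOXA4 (90.3 ± 6.04 against 17.2 ± 0.545 CPM) and HOXC4 (86.7 ± 4.87 against 16 ± 1.56 CPM) followed HOXB5. Summed CPM of paralog group 5 was 366 ± 20.9 (SD, n = 3) in the bioreactor and 12.9 ± 0.81 in adherent libraries, and that of group 4 was 412 ± 19.5 against 51.4 ± 2.66. Paralog group 9 stayed low on both platforms, at 0.54 ± 0.18 and 0.4 ± 0.23.

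**Figure D2:**
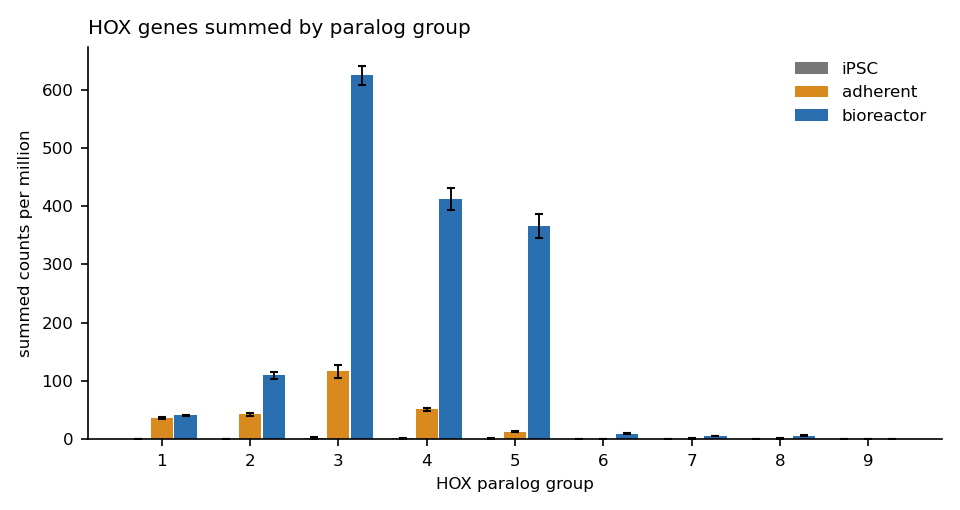
Summed CPM of the HOX genes of each paralog group in iPSC (grey), adherent (orange) and bioreactor (blue) libraries; bars are means and error bars are SD over 3 libraries. The bioreactor bars are tallest in paralog groups 3 to 5, and iPSC values stay near 0.

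Epithelial genes fell together in the bioreactor. Of epithelial junction genes, all 24 tested members fell (median log2 fold change -4.02, limma's camera adjusted p = 1.22e-09, adjusted p = 0.0311 with an estimated correlation). Among them were CLDN6 (2.75 ± 0.815 against 514 ± 26.3 CPM), the protease ST14 (-7.52), CDH1, the epithelial cadherin (30.1 ± 1.88 against 722 ± 13.1 CPM), and CLDN4 (3.63 ± 0.443 against 257 ± 21.3 CPM). For duct cell markers, 1 of 16 tested members rose, 14 fell and 1 did not pass (median log2 fold change -3.56, limma's camera adjusted p = 1.84e-05, adjusted p = 0.0311 with an estimated correlation). Examples were the keratin genes KRT18 (12.1 ± 0.773 against 1196 ± 45.2 CPM) and KRT8 (43.5 ± 2.38 against 2515 ± 54.7 CPM) beside KRT19 (ENSG00000171345, chromosome 17, 41523617 to 41528308, minus strand). Among genes of extracellular matrix and basement membrane, 2 of 25 tested members rose, 22 fell and 1 did not pass (median log2 fold change -3.52, limma's camera adjusted p = 1.17e-06, adjusted p = 0.0311 with an estimated correlation). Fibronectin, FN1, stood at 102 ± 9.2 against 4128 ± 127 CPM and the collagen IV gene COL4A1 at 10.6 ± 0.992 against 376 ± 7.7 CPM, and FBLN1 (-5.30) fell too. Of YAP target genes, 2 of 22 tested members rose and 20 fell (median log2 fold change -2.09, limma's camera adjusted p = 8.35e-06, adjusted p = 0.0311 with an estimated correlation). Examples were CCN1 at 1.99 ± 0.165 against 325 ± 13.2 CPM, AXL (-4.998) and PTPN14 (-4.05) after ANKRD1. For focal adhesion and integrin genes, 2 of 29 tested members rose, 26 fell and 1 did not pass (median log2 fold change -1.78, limma's camera adjusted p = 1.68e-06, adjusted p = 0.0822 with an estimated correlation). Examples were FLNA, an actin crosslinker, at 246 ± 5.22 against 1801 ± 71 CPM, and ITGB4 (-8.42), ACTN4 (-2.58) and CAPN2 (-2.03). Among mesenchymal cell and fibroblast markers, 5 of 23 tested members rose, 16 fell and 2 did not pass (median log2 fold change -1.73, limma's camera adjusted p = 0.0155, adjusted p = 0.171 with an estimated correlation). COL1A2 (5.79 ± 1.06 against 281 ± 7.68 CPM), COL5A1 and TAGLN fell, while THY1, which neurons also carry, rose (102 ± 4.75 against 5.96 ± 0.335 CPM).

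Of the liver genes, 2 of 18 tested members rose, 14 fell and 2 did not pass (median log2 fold change -2.95, limma's camera adjusted p = 0.000982, adjusted p = 0.0555 with an estimated correlation). Examples were AMBP (0.382 ± 0.16 against 74.2 ± 1.2 CPM), APOB (-6.22) and FGA after FGB. For intestinal genes, 2 of 12 tested members rose, 8 fell and 2 did not pass (median log2 fold change -3.06, limma's camera adjusted p = 0.0184, adjusted p = 0.0971 with an estimated correlation). Examples were the intestinal regulator CDX2 at 0.356 ± 0.0936 against 53.2 ± 0.453 CPM, CDH17 (-9.39) and KLF5 (-2.69). For stomach genes, 1 of 7 tested members rose, 5 fell and 1 did not pass (median log2 fold change -2.70, limma's camera adjusted p = 0.141; median -1.50 with genes at 0 set to their bound), and the list was not called; VSIG1 stood at 0.271 ± 0.224 against 121 ± 3.52 CPM. Among pancreatic progenitor genes, 1 of 17 tested members rose and 16 fell (median log2 fold change -1.79, limma's camera adjusted p = 0.0045, adjusted p = 0.184 with an estimated correlation). Among them were the factors GATA6 (1.51 ± 0.547 against 114.9 ± 1.87 CPM), GATA4 (-4.37) and TCF7L2 (-1.88). For acinar cell markers, 5 of 7 tested members fell and 2 did not pass (median log2 fold change -4.56, limma's camera adjusted p = 0.0305, adjusted p = 0.124 with an estimated correlation). An example was SPINK1 at 0.472 ± 0.155 against 74.8 ± 6.68 CPM. This call was lost without bioreactor replicate 3 or any 1 of the iPSC or adherent libraries, with limma's camera adjusted p from 0.057 to 0.106. Of the pluripotency genes, 4 of 26 tested members rose, 15 fell and 7 did not pass (median log2 fold change -1.11, limma's camera adjusted p = 0.0496, adjusted p = 0.253 with an estimated correlation). Among them were SCNN1A (-5.30), SALL4 (7.91 ± 0.39 against 77.7 ± 3.21 CPM), ZFP42 and TRIM71. Leaving out bioreactor replicate 1, adherent replicate 1 or 3, or any iPSC library raised limma's camera adjusted p to between 0.0525 and 0.071. The next 2 lists were not called. For mesendoderm and definitive endoderm genes, 4 of 13 tested members rose, 8 fell and 1 did not pass (median -1.65, limma's camera adjusted p = 0.568), including GATA6 (-6.24) and APELA (-3.61). For endothelial cell markers, 4 of 12 tested members rose, 4 fell and 4 did not pass (median 0.10, limma's camera adjusted p = 0.875), including EGFL7 (-1.69) and KDR (1.81).

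All genes of the cell cycle list fell: all 34 tested members fell (median log2 fold change -4.08, limma's camera adjusted p = 6.82e-12, adjusted p = 0.0857 with an estimated correlation). Examples were the mitotic genes TOP2A (7.19 ± 1.06 against 219 ± 5.43 CPM), TPX2 (-4.38) and CENPF (-4.81) beside MKI67. For cytosolic ribosomal proteins, all 34 tested members fell (median log2 fold change -1.250, limma's camera adjusted p = 1.22e-09, adjusted p = 0.233 with an estimated correlation). Examples were RPL10A at 152 ± 4.37 against 517 ± 15.2 CPM and RPS19, RPS6 and RPS3 between -1.84 and -1.57 on the log2 scale. Of the p53 targets, 1 of 21 tested members rose and 20 fell (median log2 fold change -1.59, limma's camera adjusted p = 5.34e-06, adjusted p = 0.0311 with an estimated correlation). Examples were the cell cycle inhibitor CDKN1A at 5.26 ± 0.238 against 281 ± 14.3 CPM, TNFRSF10B (-3.43), GDF15 (-6.56) and BAX (-2.22). For cholesterol synthesis genes, 22 of 23 tested members fell and 1 did not pass (median log2 fold change -0.74, limma's camera adjusted p = 1.73e-05, adjusted p = 0.0349 with an estimated correlation). An example was DHCR7 (-1.70). Among genes of interferon response, 3 of 25 tested members rose, 20 fell and 2 did not pass (median log2 fold change -1.66, limma's camera adjusted p = 0.000603, adjusted p = 0.035 with an estimated correlation). Examples were IFITM3 (-2.81), HLA-C (-2.65) and B2M (-1.84). Of the glycolysis enzymes, 5 of 19 tested members rose and 14 fell (median log2 fold change -0.96, limma's camera adjusted p = 0.0139, adjusted p = 0.253 with an estimated correlation). Examples were HK2 at 3.74 ± 0.178 against 103.5 ± 0.835 CPM and LDHA, the lactate enzyme, at 32.4 ± 1.02 against 372 ± 20.8 CPM. Nuclear genes of oxidative phosphorylation went slightly the other way: 29 of 45 tested members rose, 5 fell and 11 did not pass (median log2 fold change 0.24, limma's camera adjusted p = 0.0234, adjusted p = 0.33 with an estimated correlation). An example was NDUFS1 at 172 ± 13.7 against 98.6 ± 0.846 CPM. The mitochondrially encoded genes were split (4 of 13 tested members rose, 4 fell and 5 did not pass; median log2 fold change -0.03, limma's camera adjusted p = 0.955), with MT-ND2 higher (0.73) and MT-CO1 lower (-1.05).

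Signalling and stress lists were mostly lower or split. Genes of TGF-beta and activin response were lower (2 of 22 tested members rose, 18 fell and 2 did not pass; median log2 fold change -1.94, limma's camera adjusted p = 0.000232, adjusted p = 0.0857 with an estimated correlation), with ID1 at 6.18 ± 0.286 against 206 ± 6.5 CPM. For NOTCH response, 3 of 15 tested members rose, 11 fell and 1 did not pass (median log2 fold change -1.51, limma's camera adjusted p = 0.0301, adjusted p = 0.297 with an estimated correlation). Examples were the ligand JAG1 at 29.4 ± 1.37 against 312 ± 5.27 CPM and a rise in DTX1 (3.36). Of the hypoxia genes, 6 of 26 tested members rose, 15 fell and 5 did not pass (median log2 fold change -0.80, limma's camera adjusted p = 0.0262, adjusted p = 0.124 with an estimated correlation). Examples were VEGFA at 46.7 ± 0.888 against 254 ± 14.9 CPM and ADM (-6.83). For metallothioneins and oxidative stress, 3 of 16 tested members rose, 11 fell and 2 did not pass (median log2 fold change -1.08, limma's camera adjusted p = 0.0364, adjusted p = 0.124 with an estimated correlation). An example was TXNIP (49.4 ± 1.9 against 337 ± 2.4 CPM). This call was lost without bioreactor replicate 4 (limma's camera adjusted p = 0.0531) and with a replicate block (0.0536). The lists that follow were not called. For WNT response, 5 of 18 tested members rose, 9 fell and 4 did not pass (median -0.51, limma's camera adjusted p = 0.276), including CCND1 (-2.82) and SFRP1 (-2.76). For retinoic acid response, 6 of 19 tested members rose, 9 fell and 4 did not pass (median -0.13, limma's camera adjusted p = 0.568), including CRABP2 (-2.74) and MEIS2 (1.51). For unfolded protein response, 7 of 26 tested members rose, 17 fell and 2 did not pass (median -0.62, limma's camera adjusted p = 0.0586), including PDIA4 (-1.22) and PDIA6 (-1.11). For immediate early and heat shock genes, 9 of 24 tested members rose, 13 fell and 2 did not pass (median -0.34, limma's camera adjusted p = 0.502), including HSPB1 (-2.21) and EGR2 (6.86). For genes kept low in adult beta cells, 5 of 16 tested members rose, 10 fell and 1 did not pass (median -0.63, limma's camera adjusted p = 0.2), including MGST1 (-5.33) and HK2 (-4.79).

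In all, 6491 genes were higher and 6653 lower in the bioreactor libraries, 3029 and 3287 of them by at least 2-fold. Upper-quartile factors gave 5985 higher and 7167 lower. Libraries of the groups did not overlap for 13064 genes (82.9%), where chance gives 10%. Of the 23 tested genes chosen by name, 22 were called, 21 of them with all 3 libraries of one group beyond all 3 of the other. The exception was the pluripotency factor POU5F1 (4.18 ± 1.18 against 2.57 ± 0.866 CPM, edgeR adjusted p = 0.0134), whose call was lost without bioreactor replicate 1 (adjusted p = 0.0666) or replicate 4 (0.0561) and with the replicate number as a replicate block (0.131). NANOG, at 0.361 ± 0.13 against 0.208 ± 0.142 CPM, did not pass (edgeR adjusted p = 0.166), and UCN3, a gene of mature beta cells, had too few counts to test. Among the 41 lists, 6 were called higher and 21 lower, and 8 of these calls held with an estimated correlation: hormone granules and exocytosis, duct cell markers, extracellular matrix and basement membrane, epithelial junction genes, YAP target genes, p53 targets, cholesterol synthesis genes and interferon response.

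**Figure D3:**
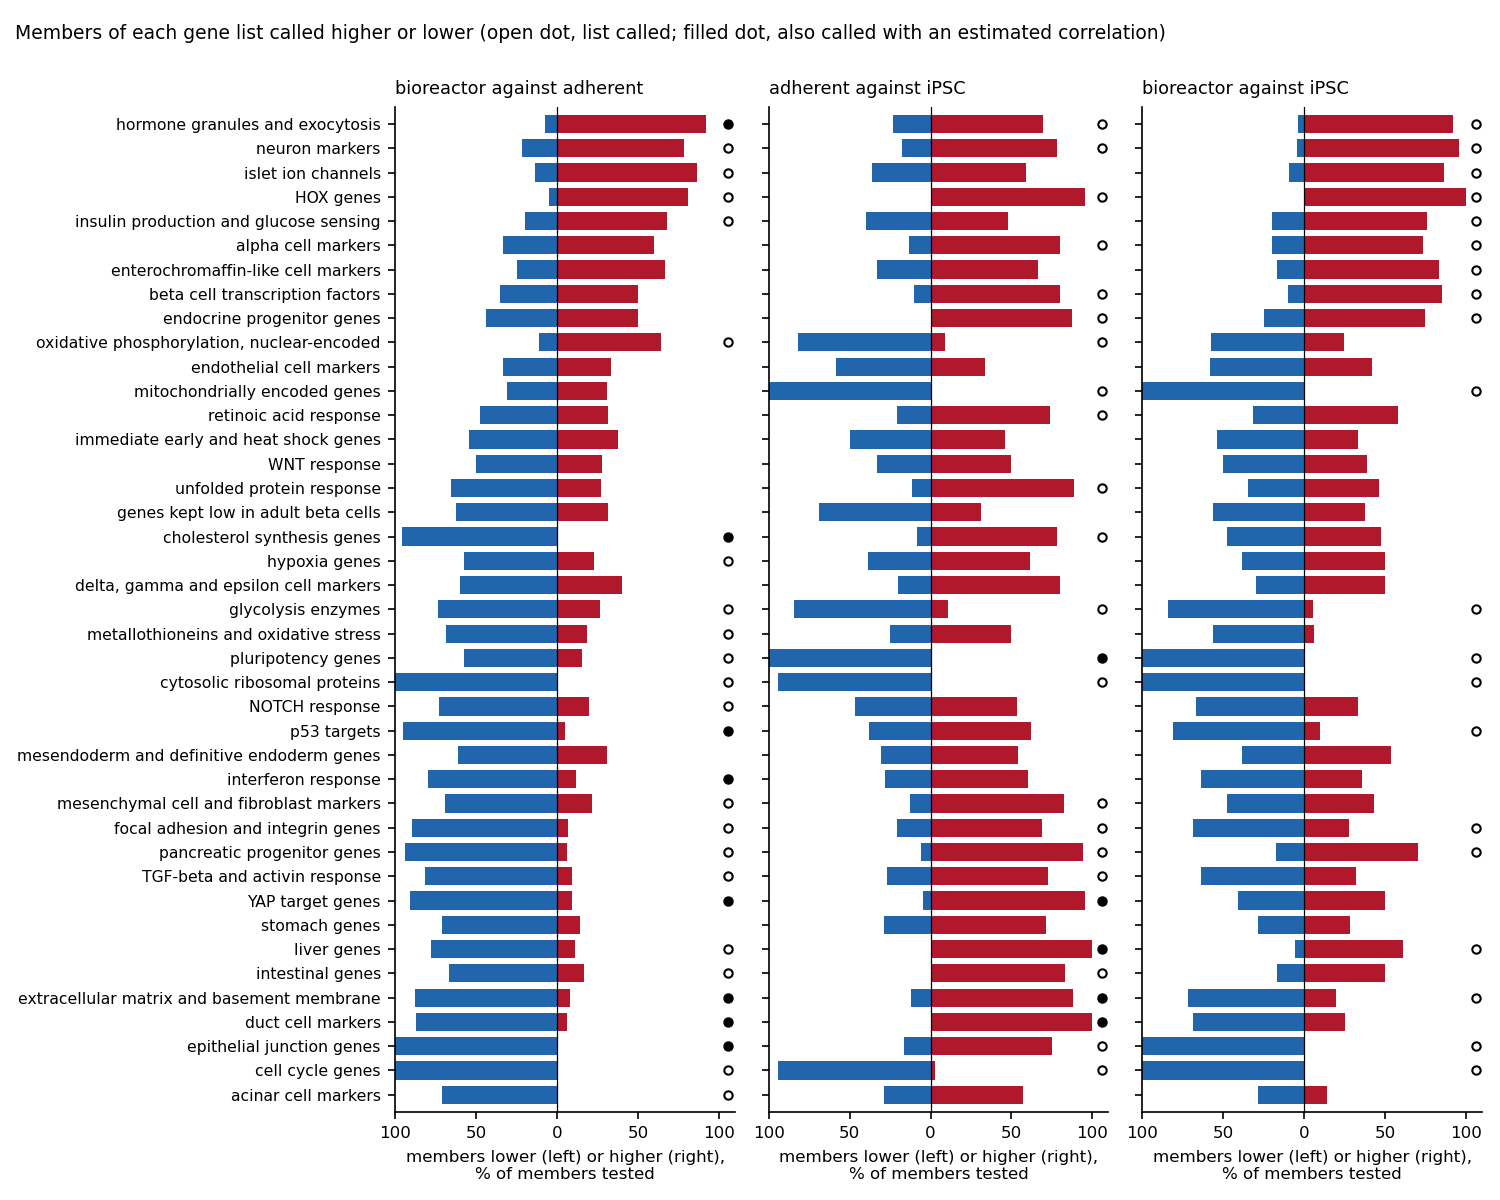
Percent of tested members called higher (red, to the right) or lower (blue, to the left) for the 41 gene lists in the 3 comparisons, ordered by their median log2 fold change between bioreactor and adherent libraries. Open dots mark lists called by camera with the preset correlation of 0.01 and filled dots those also called with an estimated correlation, of which there were 8, 5 and 0.

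The comparison of adherent with iPSC libraries shows the change from the starting cells on plates, within libraries whose titles name 1 experiment. Pluripotency genes were lower in the adherent libraries, with POU5F1, a core factor of the pluripotent state, at 2.57 ± 0.866 against 1462 ± 1.91 CPM (SD, n = 3) and NANOG at 0.208 ± 0.142 against 76 ± 2.82 CPM. AFP, a fetal liver gene, was higher at 679 ± 38.6 against 0.434 ± 0.0674 CPM, and KRT19 at 862 ± 31.4 against 103.6 ± 3.64 CPM. The hormone genes INS (21.6 ± 2.03 against 0.117 ± 0.153 CPM) and GCG (33.8 ± 2.45 against 0.516 ± 0.617 CPM) rose from near 0 to low levels. PDX1 and NKX6-1 rose as well, the first at least 157-fold from 0 counts and the second to 43.8 ± 2.73 against 0.373 ± 0.202 CPM.

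The 8 largest rises by edgeR were led by FGB, which stood at 715 ± 53.8 CPM and was at least 12100-fold higher, since all 3 iPSC libraries had 0 counts. The adhesion gene CEACAM6 (at least 3360-fold), the mucosal disulfide isomerase AGR2 (at least 1200-fold), the protease HABP2 (at least 1180-fold), the keratin gene KRT4 (at least 1020-fold) and the fibrinogen chain FGA (at least 610-fold) also came from 0 counts. AREG rose by a ratio of 10600 (95% counting interval 1900 to 418000), and ANKRD1 to 462 ± 40 against 0.0985 ± 0.0339 CPM. The 8 largest falls were in HES3, a repressor of the HES family (at least 465-fold), IDO1, a tryptophan-degrading enzyme (-9.57), ZSCAN10 (-9.45), POU5F1 (-9.16), VRTN (-8.96), the NODAL coreceptor TDGF1 (-8.78), NANOG (-8.47) and the homeobox gene OTX2 (-8.29). Among the other genes chosen by name, INS (7.42, edgeR adjusted p = 1.39e-07), GCG (6.02, 2.21e-07), NKX2-2 (higher by a ratio of 101, 95% counting interval 27.6 to 839), NEUROD1 (higher by a ratio of 174, 95% counting interval 30.9 to 6920), CHGA (2.46), NEUROG3 (1.61), TPH1 (2.89), SOX9 (0.41), ALB (3.60) and COL1A1 (1.28) rose. SST rose by a ratio of 246 (95% counting interval 83.7 to 1190), while SOX2 (-1.05) and MKI67 (-1.21) fell. IAPP (0.0746 ± 0.0302 against 0.118 ± 0.102 CPM, edgeR adjusted p = 0.505) and MAFA (1.41 ± 0.17 against 1.18 ± 0.158 CPM, edgeR adjusted p = 0.341) did not pass.

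Among the lists, pluripotency genes fell: all 26 tested members fell (median log2 fold change -5.01, limma's camera adjusted p = 2.22e-09, adjusted p = 0.0317 with an estimated correlation). Examples were DNMT3B at 24.7 ± 1.1 against 1422 ± 27.7 CPM and DPPA4 at 28.6 ± 1.93 against 1038 ± 27.3 CPM. For liver genes, all 18 tested members rose (median log2 fold change 7.33, limma's camera adjusted p = 2.91e-07, adjusted p = 0.0317 with an estimated correlation; median 7.16 with genes at 0 set to their bound). Examples were VTN at 92.5 ± 1.7 against 0.0781 ± 0.0885 CPM and APOA1 at 51.4 ± 0.975 against 0.492 ± 0.0816 CPM. Of duct cell markers, all 16 tested members rose (median log2 fold change 3.12, limma's camera adjusted p = 4.93e-06, adjusted p = 0.0317 with an estimated correlation). Examples were S100A10 at 262 ± 19.1 against 24.2 ± 0.918 CPM and KRT8 at 2515 ± 54.7 against 363 ± 11.6 CPM. For YAP target genes, 21 of 22 tested members rose and 1 fell (median log2 fold change 1.78, limma's camera adjusted p = 2.15e-06, adjusted p = 0.0317 with an estimated correlation). An example was MYOF at 354 ± 1.41 against 3.53 ± 0.0987 CPM. Among genes of extracellular matrix and basement membrane, 22 of 25 tested members rose and 3 fell (median log2 fold change 1.87, limma's camera adjusted p = 1.93e-05, adjusted p = 0.0468 with an estimated correlation). Examples were FN1 at 4128 ± 127 against 85.3 ± 3.37 CPM and LAMB1 at 1118 ± 12.6 against 99.3 ± 7.15 CPM. For mesenchymal cell and fibroblast markers, 19 of 23 tested members rose, 3 fell and 1 did not pass (median log2 fold change 2.24, limma's camera adjusted p = 0.000473, adjusted p = 0.127 with an estimated correlation). Examples were VIM at 2047 ± 79.8 against 108 ± 1.05 CPM and a fall in THY1 (-6.12). Of intestinal genes, 10 of 12 tested members rose and 2 did not pass (median log2 fold change 5.80, limma's camera adjusted p = 0.000774, adjusted p = 0.0619 with an estimated correlation). An example was CDX2 at 53.2 ± 0.453 against 0.0788 ± 0.0909 CPM.

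For pancreatic progenitor genes, 16 of 17 tested members rose and 1 fell (median log2 fold change 5.43, limma's camera adjusted p = 5.07e-05, adjusted p = 0.127 with an estimated correlation). Examples were FOXA1, a pioneer factor of the gut tube, at 246 ± 2.2 against 0.313 ± 0.24 CPM and GATA6 at 114.9 ± 1.87 against 0.158 ± 0.136 CPM. Of beta cell transcription factors, 16 of 20 tested members rose, 2 fell and 2 did not pass (median log2 fold change 4.996, limma's camera adjusted p = 0.000192, adjusted p = 0.163 with an estimated correlation). Examples were GLIS3 at 43 ± 3.12 against 0.412 ± 0.205 CPM and RFX6 at 17.7 ± 0.623 against 0.0988 ± 0.0688 CPM. For endocrine progenitor genes, 14 of 16 tested members rose and 2 did not pass (median log2 fold change 2.15, limma's camera adjusted p = 0.000152, adjusted p = 0.127 with an estimated correlation). An example was INSM1 at 16.8 ± 0.514 against 1.22 ± 0.125 CPM. For alpha cell markers, 12 of 15 tested members rose, 2 fell and 1 did not pass (median log2 fold change 3.73, limma's camera adjusted p = 0.00397, adjusted p = 0.186 with an estimated correlation). Among hormone granules and exocytosis, 18 of 26 tested members rose, 6 fell and 2 did not pass (median log2 fold change 1.18, limma's camera adjusted p = 0.0257, adjusted p = 0.245 with an estimated correlation); SNAP25 rose (4.44) and UNC13A fell (-3.44). Neuron markers moved the same way: 18 of 23 tested members rose, 4 fell and 1 did not pass (median log2 fold change 2.69, limma's camera adjusted p = 0.00397, adjusted p = 0.302 with an estimated correlation). Examples were the axonal gene CNTN2 at 124 ± 4.38 against 2.88 ± 0.157 CPM and NEFL at 506 ± 28 against 38.8 ± 2.99 CPM. For HOX genes, 20 of 21 tested members rose and 1 did not pass (median log2 fold change 5.01, limma's camera adjusted p = 5.07e-05, adjusted p = 0.163 with an estimated correlation; median 4.84 with genes at 0 set to their bound). An example was HOXA4 (6.14). For retinoic acid response, 14 of 19 tested members rose, 4 fell and 1 did not pass (median log2 fold change 2.12, limma's camera adjusted p = 0.012, adjusted p = 0.227 with an estimated correlation). An example was MEIS2 at 240.3 ± 3.92 against 2.55 ± 0.857 CPM.

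Growth and energy lists were lower than in iPSC. Of cell cycle genes, 1 of 34 tested members rose, 32 fell and 1 did not pass (median log2 fold change -1.47, limma's camera adjusted p = 1.71e-07, adjusted p = 0.163 with an estimated correlation). Examples were BUB1 at 41.9 ± 2.33 against 277 ± 7.33 CPM and MCM3 at 108 ± 3.36 against 424 ± 6.61 CPM. For cytosolic ribosomal proteins, 32 of 34 tested members fell and 2 did not pass (median log2 fold change -0.54, limma's camera adjusted p = 2.34e-06, adjusted p = 0.302 with an estimated correlation). Examples were RPL8 (-0.77) and RPL4 (-0.74). Of mitochondrially encoded genes, all 13 tested members fell (median log2 fold change -1.26, limma's camera adjusted p = 7.33e-05, adjusted p = 0.297 with an estimated correlation), and MT-CO3 stood at 2597 ± 193 against 8031 ± 554 CPM. Among nuclear genes of oxidative phosphorylation, 4 of 45 tested members rose, 37 fell and 4 did not pass (median log2 fold change -0.43, limma's camera adjusted p = 5.07e-05, adjusted p = 0.174 with an estimated correlation), and SDHD stood at 32 ± 0.819 against 74.5 ± 2.23 CPM. For glycolysis enzymes, 2 of 19 tested members rose, 16 fell and 1 did not pass (median log2 fold change -0.67, limma's camera adjusted p = 0.000527, adjusted p = 0.194 with an estimated correlation). Examples were SLC16A1 (-1.73) and PGK1 (-1.10). Smaller rises were called for 5 lists. For unfolded protein response, 23 of 26 tested members rose and 3 fell (median 0.71, limma's camera adjusted p = 0.000527, adjusted p = 0.127 with an estimated correlation), including SEL1L (1.64) and TRIB3 (2.58). Of cholesterol synthesis genes, 18 of 23 tested members rose, 2 fell and 3 did not pass (median 0.79, limma's camera adjusted p = 0.000965, adjusted p = 0.0988 with an estimated correlation), including LSS (1.52) and TM7SF2 (1.41). For epithelial junction genes, 18 of 24 tested members rose, 4 fell and 2 did not pass (median 0.55, limma's camera adjusted p = 0.0163, adjusted p = 0.174 with an estimated correlation), including ST14 (2.20) and CLDN4 (2.35). Among focal adhesion and integrin genes, 20 of 29 tested members rose, 6 fell and 3 did not pass (median 0.96, limma's camera adjusted p = 0.00688, adjusted p = 0.227 with an estimated correlation), including CAPN2 (2.63) and ITGAV (2.24). For TGF-beta and activin response, 16 of 22 tested members rose and 6 fell (median 1.09, limma's camera adjusted p = 0.0267, adjusted p = 0.227 with an estimated correlation), including ID2 (2.03) and LTBP3 (3.05). The call for TGF-beta and activin response was lost with library totals as the only scaling (limma's camera adjusted p = 0.0569).

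The remaining lists were not called between adherent and iPSC libraries. For insulin production and glucose sensing, 12 of 25 tested members rose, 10 fell and 3 did not pass (median 0.17, limma's camera adjusted p = 0.549), including CPE (4.18) and PAM (2.59). Of islet ion channels, 13 of 22 tested members rose, 8 fell and 1 did not pass (median 0.59, limma's camera adjusted p = 0.528), including SCN8A (-2.26) and SCN3B (4.27). For delta, gamma and epsilon cell markers, 8 of 10 tested members rose and 2 fell (median 1.57, limma's camera adjusted p = 0.142), including ETV1 (-2.69) and SST (higher by a ratio of 246, 95% counting interval 83.7 to 1190). Of enterochromaffin-like cell markers, 8 of 12 tested members rose and 4 fell (median 2.08, limma's camera adjusted p = 0.148), including DDC (7.57) and MME (-2.77). For acinar cell markers, 4 of 7 tested members rose, 2 fell and 1 did not pass (median 3.97, limma's camera adjusted p = 0.32), including SPINK1 (9.22) and PRSS2 (at least 34.9-fold higher). Of stomach genes, 5 of 7 tested members rose and 2 fell (median 1.05, limma's camera adjusted p = 0.32), including VSIG1 (6.59) and CLDN18 (4.55). For mesendoderm and definitive endoderm genes, 7 of 13 tested members rose, 4 fell and 2 did not pass (median 1.43, limma's camera adjusted p = 0.549), including APELA (-2.85) and GATA6 (9.44). Of endothelial cell markers, 4 of 12 tested members rose, 7 fell and 1 did not pass (median -0.81, limma's camera adjusted p = 0.242), including KDR (-3.77) and TEK (-2.80).

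For hypoxia genes, 16 of 26 tested members rose and 10 fell (median 0.63, limma's camera adjusted p = 0.223), including VEGFA (2.16) and SLC2A3 (-1.80). Of immediate early and heat shock genes, 11 of 24 tested members rose, 12 fell and 1 did not pass (median -0.01, limma's camera adjusted p = 0.465), including EGR1 (-3.72) and FOSB (-5.89). For interferon response, 15 of 25 tested members rose, 7 fell and 3 did not pass (median 0.78, limma's camera adjusted p = 0.134), including IFITM1 (-3.14) and BST2 (-4.38). Of p53 targets, 13 of 21 tested members rose and 8 fell (median 0.71, limma's camera adjusted p = 0.271), including CDKN1A (2.57) and GDF15 (3.26). For NOTCH response, 8 of 15 tested members rose and 7 fell (median 0.50, limma's camera adjusted p = 0.624), including JAG1 (1.71) and DLL1 (2.04). Of WNT response, 9 of 18 tested members rose, 6 fell and 3 did not pass (median 0.95, limma's camera adjusted p = 0.515), including SFRP2 (-5.73) and TNFRSF19 (3.996). For metallothioneins and oxidative stress, 8 of 16 tested members rose, 4 fell and 4 did not pass (median 0.22, limma's camera adjusted p = 0.528), including TXNIP (2.78) and MT1X (-3.34). Of genes kept low in adult beta cells, 5 of 16 tested members rose and 11 fell (median -0.77, limma's camera adjusted p = 0.107), including CXCL12 (-4.09) and SLC16A1 (-1.73). The median of the immediate early list was -0.01, and 0.14 with library totals as the only scaling, 0.02 with upper-quartile factors and 0 with RLE size factors.

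In this comparison 6676 genes were higher and 6476 lower in the adherent libraries, 3457 and 2425 of them by at least 2-fold. With library totals as the only scaling, 7585 were higher and 5585 lower. Libraries of the groups did not overlap for 13349 genes (84.7%), where chance gives 10%. All 21 called genes among the 23 chosen by name had all 3 libraries of one group beyond those of the other. Of the 41 lists, 19 were called higher and 6 lower, and 5 calls held with an estimated correlation: duct cell markers, pluripotency genes, liver genes, YAP target genes and extracellular matrix and basement membrane. Adjusted over the list alone, the counts were the same for every list, except that 3 glycolysis enzymes rose and 38 nuclear genes of oxidative phosphorylation fell.

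The comparison of bioreactor with iPSC libraries sets suspension culture against undifferentiated cells whose titles name another experiment. It therefore mixes differentiation with any difference between the experiments. Islet hormones rose far above the iPSC level: GCG stood at 1475 ± 34.4 against 0.516 ± 0.617 CPM (SD, n = 3), INS at 122 ± 16.4 against 0.117 ± 0.153 CPM, and SST was higher by a ratio of 2090 (95% counting interval 716 to 10200). TTR, a thyroid hormone carrier made by liver and alpha cells, stood at 965 ± 46.8 against 0.476 ± 0.493 CPM. Pluripotency and cell cycle genes fell, with POU5F1 at 4.18 ± 1.18 against 1462 ± 1.91 CPM and MKI67 at 4.78 ± 1.14 against 409 ± 3.17 CPM. KRT19 (5.86 ± 0.716 against 103.6 ± 3.64 CPM) and COL1A1 (8.68 ± 3.44 against 141 ± 6.23 CPM) fell below the iPSC level.

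Beside GCG (11.47, edgeR adjusted p = 1.13e-10), TTR (10.97) and SST, the 8 largest rises held neuronal genes: CACNG2, an AMPA receptor accessory subunit (at least 803-fold, 47.4 ± 1.89 CPM), LGI3 (223 ± 16.1 against 0.0785 ± 0.0326 CPM) and CNTN6, a neuronal adhesion gene (ratio 1770, 95% counting interval 489 to 14600). CFC1, a NODAL coreceptor, was at least 1880-fold higher (111 ± 6.61 CPM), though its near-identical copy CFC1B makes its share of the reads uncertain. GDF1, a growth factor gene, had 0 counts in iPSC and was higher in the bioreactor (edgeR adjusted p = 0.0116), but it overlaps CERS1, so its own share of the reads is uncertain and no fold is given. The sum of GDF1 and CERS1 was 403, 445 and 467 counts in iPSC and 1410, 1771 and 1380 in bioreactor libraries. In the adherent libraries GDF1 had 313, 0 and 153 counts while the sum was 471, 438 and 459. The GDF1 call was lost with limma voom (adjusted p = 0.0871) and with a replicate block (0.0637). The 8 largest falls were in NMRK2, a nicotinamide riboside kinase (ratio 2050, 95% counting interval 368 to 81100), TRIML2 (ratio 1810, 95% counting interval 324 to 71400), CUZD1 (ratio 1080, 95% counting interval 193 to 42500), ACTN3, a muscle actinin (ratio 741, 95% counting interval 253 to 3590), IDO1 (-9.49), the kinase gene LCK (-8.95), TDGF1 (-8.67) and OTX2 (-8.65). Among genes chosen by name, PDX1 rose at least 54.5-fold, and INS (9.92), IAPP (5.95), NKX6-1 (8.41), NKX2-2 (higher by a ratio of 238, 95% counting interval 65.4 to 1970), NEUROD1 (higher by a ratio of 718, 95% counting interval 128 to 28400), MAFA (3.88), CHGA (4.78), NEUROG3 (2.91) and TPH1 (7.07) rose. SOX2 (-2.13), SOX9 (-0.41) and NANOG (-7.70) fell, while ALB (0.461 ± 0.108 against 0.257 ± 0.0377 CPM, edgeR adjusted p = 0.098) and AFP (0.582 ± 0.493 against 0.434 ± 0.0674 CPM, edgeR adjusted p = 0.441) did not pass. The sign for AFP turned without bioreactor replicate 4 (log2 fold change -0.54) and with a replicate block (-0.50).

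The lists below rose from iPSC in the bioreactor. Among hormone granules and exocytosis, 24 of 26 tested members rose, 1 fell and 1 did not pass (median log2 fold change 3.50, limma's camera adjusted p = 5.6e-07, adjusted p = 0.116 with an estimated correlation). Examples were SNAP25 at 357 ± 11.1 against 1 ± 0.395 CPM and SCG2 at 232 ± 7.24 against 1.77 ± 0.451 CPM. Neuron markers moved with them: 22 of 23 tested members rose and 1 fell (median log2 fold change 4.73, limma's camera adjusted p = 2.25e-06, adjusted p = 0.198 with an estimated correlation). Examples were MAP2 at 1714 ± 77.3 against 47.3 ± 3.79 CPM and GAP43 at 551 ± 9.97 against 12.7 ± 1.93 CPM. For HOX genes, all 21 tested members rose (median log2 fold change 7.87, limma's camera adjusted p = 8.68e-06, adjusted p = 0.172 with an estimated correlation; median 7.76 with genes at 0 set to their bound). An example was HOXA5 at 41 ± 0.802 against 0.296 ± 0.0621 CPM. Of beta cell transcription factors, 17 of 20 tested members rose, 2 fell and 1 did not pass (median log2 fold change 6.24, limma's camera adjusted p = 0.000219, adjusted p = 0.183 with an estimated correlation; bounded median 6.06). An example was MYT1 at 67.6 ± 0.645 against 3.13 ± 0.428 CPM. For insulin production and glucose sensing, 19 of 25 tested members rose, 5 fell and 1 did not pass (median log2 fold change 2.69, limma's camera adjusted p = 0.00906, adjusted p = 0.131 with an estimated correlation; bounded median 2.53). Examples were CPE at 595 ± 13.4 against 18.9 ± 2.28 CPM and a fall in the glucose transporter SLC2A1 (-2.83). For islet ion channels, 19 of 22 tested members rose, 2 fell and 1 did not pass (median 2.14, limma's camera adjusted p = 0.000794, adjusted p = 0.249 with an estimated correlation), including SCN3B (7.85) and ITPR3 (-4.96). Of enterochromaffin-like cell markers, 10 of 12 tested members rose and 2 fell (median 6.25, limma's camera adjusted p = 0.016, adjusted p = 0.159 with an estimated correlation), including TAC1 (7.99) and DDC (9.22). The median of that list was 4.87 with genes at 0 set to their bound. Among endocrine progenitor genes, 12 of 16 tested members rose and 4 fell (median 3.33, limma's camera adjusted p = 0.0201, adjusted p = 0.283 with an estimated correlation), including CBFA2T3 (4.10) and INSM1 (4.56). For liver genes, 11 of 18 tested members rose, 1 fell and 6 did not pass (median 3.25, limma's camera adjusted p = 0.0266, adjusted p = 0.183 with an estimated correlation), including SERPINA1 (8.45) and ITIH2 (higher by a ratio of 463, 95% counting interval 82.7 to 18300). Its bounded median was 2.602. Of alpha cell markers, 11 of 15 tested members rose, 3 fell and 1 did not pass (median 3.27, limma's camera adjusted p = 0.0397, adjusted p = 0.323 with an estimated correlation), including KCTD12 (3.27) and GC (higher by a ratio of 512, 95% counting interval 175 to 2490). The bounded median was 3.23 here. Among pancreatic progenitor genes, 12 of 17 tested members rose, 3 fell and 2 did not pass (median 3.20, limma's camera adjusted p = 0.0429, adjusted p = 0.343 with an estimated correlation), including FOXA1 (9.28) and TCF7L2 (-2.79). With library totals as the only scaling, limma's camera no longer called alpha cell markers (adjusted p = 0.0553) or pancreatic progenitor genes (0.0629).

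Lists of growth, epithelial and pluripotent genes fell. Of cell cycle genes, all 34 tested members fell (median log2 fold change -5.57, limma's camera adjusted p = 2.99e-11, adjusted p = 0.159 with an estimated correlation). Examples were TOP2A at 7.19 ± 1.06 against 611 ± 19.6 CPM and BUB1 (-7.31). For cytosolic ribosomal proteins, all 34 tested members fell (median log2 fold change -1.78, limma's camera adjusted p = 1.96e-09, adjusted p = 0.283 with an estimated correlation). An example was RPS6 at 252 ± 5.72 against 1390 ± 82.9 CPM. Of pluripotency genes, all 26 tested members fell (median log2 fold change -6.67, limma's camera adjusted p = 1.92e-08, adjusted p = 0.0933 with an estimated correlation). Examples were DNMT3B (-6.98) and PODXL at 103.8 ± 3.61 against 2775 ± 76.3 CPM. For epithelial junction genes, all 24 tested members fell (median log2 fold change -3.31, limma's camera adjusted p = 2.57e-07, adjusted p = 0.0933 with an estimated correlation). Examples were CLDN6 at 2.75 ± 0.815 against 507 ± 9.41 CPM and ESRP1, an epithelial splicing factor, at 3.74 ± 0.312 against 229.6 ± 6.92 CPM. For glycolysis enzymes, 1 of 19 tested members rose, 16 fell and 2 did not pass (median -1.61, limma's camera adjusted p = 0.00027, adjusted p = 0.198 with an estimated correlation), including SLC16A1 (-4.39) and LDHA (-4.39). Of mitochondrially encoded genes, all 13 tested members fell (median -1.23, limma's camera adjusted p = 0.000961, adjusted p = 0.425 with an estimated correlation), including MT-CO3 (-1.97) and MT-CO1 (-1.88). For p53 targets, 2 of 21 tested members rose, 17 fell and 2 did not pass (median -0.92, limma's camera adjusted p = 0.00184, adjusted p = 0.116 with an estimated correlation), including AEN (-3.21) and DDB2 (-3.80). Among extracellular matrix and basement membrane, 5 of 25 tested members rose, 18 fell and 2 did not pass (median -1.64, limma's camera adjusted p = 0.00957, adjusted p = 0.172 with an estimated correlation), including FBLN1 (-4.11) and COL4A1 (-3.73). For focal adhesion and integrin genes, 8 of 29 tested members rose, 20 fell and 1 did not pass (median -1.31, limma's camera adjusted p = 0.031, adjusted p = 0.343 with an estimated correlation), including VCL (-3.24) and ITGAV (3.12). Its median was -1.23 with genes at 0 set to their bound. Of duct cell markers, 4 of 16 tested members rose, 11 fell and 1 did not pass (median log2 fold change -1.34, limma's camera adjusted p = 0.0559); this list was called without bioreactor replicate 1 (adjusted p = 0.0479) and without iPSC replicate 3 (0.038), and with library totals (0.049). For mesenchymal cell and fibroblast markers, 10 of 23 tested members rose, 11 fell and 2 did not pass (median -0.14, limma's camera adjusted p = 0.972), including COL1A2 (-4.58) and VIM (3.09). Of YAP target genes, 11 of 22 tested members rose, 9 fell and 2 did not pass (median 0.27, limma's camera adjusted p = 0.764), including CCN1 (-6.14) and PTPN14 (-3.82). For hypoxia genes, 13 of 26 tested members rose, 10 fell and 3 did not pass (median 0.34, limma's camera adjusted p = 0.818), including AK4 (-5.18) and LDHA (-4.39). None of the last 3 was called, and camera put all 3 up while the mean log2 fold change was 0.74, -0.07 and -0.49, so median, mean and test differed in sign.

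The remaining lists were not called between bioreactor and iPSC libraries. For delta, gamma and epsilon cell markers, 5 of 10 tested members rose, 3 fell and 2 did not pass (median 0.05, limma's camera adjusted p = 0.744), including SST (higher by a ratio of 2090, 95% counting interval 716 to 10200) and ETV1 (-2.26). Of acinar cell markers, 1 of 7 tested members rose, 2 fell and 4 did not pass (median -0.26, limma's camera adjusted p = 0.613), including RBPJL (at least 29.1-fold lower) and BHLHA15 (-2.08). For stomach genes, 2 of 7 tested members rose, 2 fell and 3 did not pass (median -0.18, limma's camera adjusted p = 0.951), including BARX1 (at least 27.7-fold lower) and IRX5 (1.49). Of intestinal genes, 6 of 12 tested members rose, 2 fell and 4 did not pass (median 1.11, limma's camera adjusted p = 0.262), including KLF5 (3.10) and TFF3 (8.42). For mesendoderm and definitive endoderm genes, 7 of 13 tested members rose, 5 fell and 1 did not pass (median 2.08, limma's camera adjusted p = 0.725), including APELA (-6.46) and STC1 (-5.08). Of endothelial cell markers, 5 of 12 tested members rose and 7 fell (median -1.60, limma's camera adjusted p = 0.418), including KDR (-1.97) and EGFL7 (-2.11). For retinoic acid response, 11 of 19 tested members rose, 6 fell and 2 did not pass (median 1.92, limma's camera adjusted p = 0.194), including MEIS2 (8.06) and ALDH1A1 (5.11). Of oxidative phosphorylation, nuclear-encoded, 11 of 45 tested members rose, 26 fell and 8 did not pass (median -0.15, limma's camera adjusted p = 0.167), including SDHD (-1.77) and CYC1 (-0.93). For unfolded protein response, 12 of 26 tested members rose, 9 fell and 5 did not pass (median 0.09, limma's camera adjusted p = 0.613), including SEL1L (2.19) and HERPUD1 (2.87).

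For cholesterol synthesis genes, 11 of 23 tested members rose, 11 fell and 1 did not pass (median -0.06, limma's camera adjusted p = 0.613), including FDFT1 (-1.48) and STARD4 (-1.56). Of immediate early and heat shock genes, 8 of 24 tested members rose, 13 fell and 3 did not pass (median -0.27, limma's camera adjusted p = 0.232), including EGR1 (-4.34) and IER2 (-3.11). For interferon response, 9 of 25 tested members rose and 16 fell (median -0.84, limma's camera adjusted p = 0.186), including IFITM1 (-8.08) and IFITM3 (-3.53). Of NOTCH response, 5 of 15 tested members rose and 10 fell (median -1.65, limma's camera adjusted p = 0.31), including NOTCH1 (-4.50) and NRARP (-4.08). For WNT response, 7 of 18 tested members rose, 9 fell and 2 did not pass (median -0.48, limma's camera adjusted p = 0.583), including SFRP1 (-4.66) and SFRP2 (-4.74). Of TGF-beta and activin response, 7 of 22 tested members rose, 14 fell and 1 did not pass (median -0.46, limma's camera adjusted p = 0.181), including TGIF1 (-4.17) and ID1 (-4.47). For metallothioneins and oxidative stress, 1 of 16 tested members rose, 9 fell and 6 did not pass (median -0.45, limma's camera adjusted p = 0.149), including SLC7A11 (-3.24) and GPX3 (1.89). Of genes kept low in adult beta cells, 6 of 16 tested members rose, 9 fell and 1 did not pass (median -0.98, limma's camera adjusted p = 0.269), including MGST1 (-6.45) and SLC16A1 (-4.39). The median of the cholesterol list turned from -0.06 to 0.08 with library totals as the only scaling.

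Relative to iPSC, 6931 genes were higher and 6996 lower in the bioreactor libraries, 4334 and 4023 of them by at least 2-fold. Scaling by library totals alone gave 7487 and 6408. Libraries did not overlap for 13956 genes (88.6%), where chance gives 10%. Each of the 21 genes called among the 23 chosen by name had non-overlapping libraries. Of the 41 lists, 11 were called higher and 9 lower, and 0 of these calls held with an estimated correlation, while fry, which tests whether a list's own genes move one way, called 16 higher and 25 lower. Adjusted over the list alone, the counts were the same for every list, except that 4 delta, gamma and epsilon cell markers and 10 liver genes rose.

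Many genes were called in the same direction from iPSC on both platforms. Genes higher on both numbered 4798, where independent calls would give 2937, and those lower on both numbered 4958, against 2875. The shared genes include POU5F1 and MKI67 among the falls and INS and GCG among the rises. Another 2160 genes moved in opposite directions. Across the 15757 genes, which are not independent replicates, the log2 fold changes of the platforms had a Pearson r of 0.645, against a mean of 0.471 in 20 simulated sets of unchanged groups measured against the same iPSC libraries. Their covariance was 3.26 against 0.017 in those sets, in which at most 2 genes were called the same way. The iPSC libraries serve both comparisons, so part of this r comes from the shared control. For the same reason the calls were not independent, since a gene particular to iPSC moves the same way in both. The simulated groups did not differ from iPSC, so they do not show how much sharing unrelated end states would give. How far the platforms shared a path was therefore not tested.

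**Figure D4:**
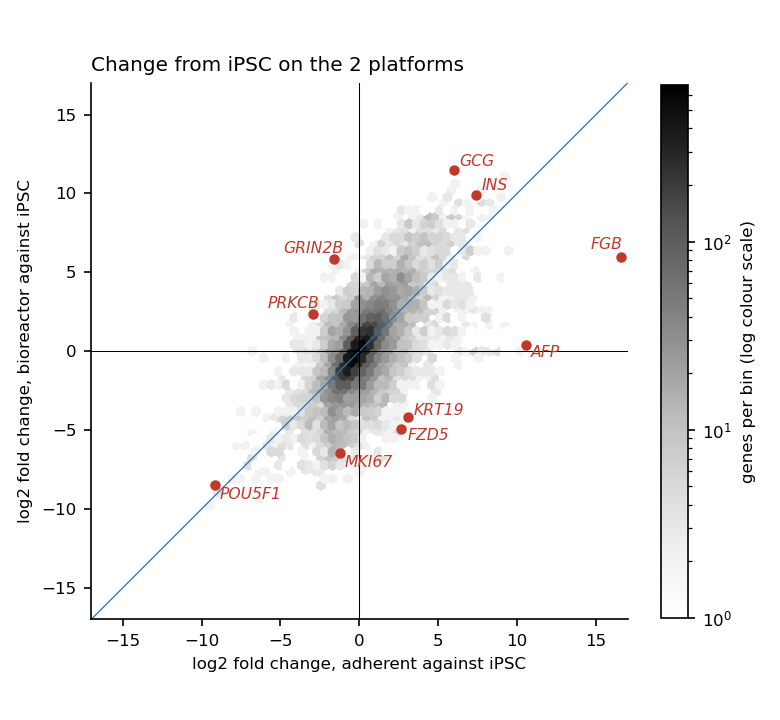
Log2 fold change from iPSC of each tested gene in adherent (horizontal axis) and bioreactor (vertical axis) libraries, binned in hexagons shaded by the number of genes on a log scale; named genes are red dots and the blue line marks equal change. GCG and INS rise on both platforms, and KRT19 and FZD5 rise in adherent and fall in bioreactor libraries.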

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

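In this part, the test of iPSC left in the adherent libraries and the split of the beta cell transcription factors were chosen after the result was seen, as were the interneuron and transmitter lists, less members already seen, and the choice to set the transmitter test aside. The platforms moved 956 genes up in bioreactor and down in adherent libraries relative to iPSC, and 1204 the other way, with a called difference between the platforms. Among the first, the log2 fold change between platforms was 5.28 for PRKCB, a protein kinase C (172 ± 6.77 CPM in bioreactor, 4.42 ± 0.673 in adherent and 33.6 ± 1.65 in iPSC libraries), 4.48 for the synaptic adhesion gene CADM2, 4.39 for OLFM1 and 4.11 for NAP1L2. Among the second, it was -7.20 for KRT19 (5.86 ± 0.716 CPM in bioreactor, 862 ± 31.4 in adherent and 103.6 ± 3.64 in iPSC libraries), -6.23 for the basement membrane gene HSPG2, -5.85 for KRT8 and -7.56 for the WNT receptor FZD5.

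Of 23 tested neuron markers, 18 rose and 5 fell in the bioreactor (limma's camera adjusted p = 0.253 with an estimated correlation, so the call was lost), with MAP2 (1714 ± 77.3 against 138 ± 2.9 CPM), NEFL (912 ± 45.8 against 506 ± 28 CPM) and TUBB3 (844 ± 35.4 against 542 ± 27.9 CPM), and 3 of the list's 24 members are also in other lists. Gene length and GC content are argued against: the list's median of 2.59 stood at percentile 100 of 10000 matched random lists, whose highest median was 1.14. Islet cells that use neuronal genes stay open, because 50% of the 16 remaining interneuron factors were higher (8 higher, 6 lower), between the bounds set beforehand. The share does not weigh sizes, as PAX2 stood at 241 ± 15.3 against 3.16 ± 0.224 CPM and GATA3 at 0.577 ± 0.244 against 18.8 ± 0.783 CPM. It is also relative to adherent libraries. With seen members included, 16 of 21 tested factors were higher there than in iPSC, and 20 of 21 in the bioreactor. Neural cells of the spinal cord or hindbrain stay open too: 94.7% of the 38 remaining transmitter genes (36) were higher, but islet cells that use neuronal genes could raise such genes as well. Bulk libraries do not show which cells held these transcripts.

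Sharing with the ventral neural tube or neurons could explain why beta cell transcription factors went both ways. The 11 set as shared had a median of 1.23 (8 higher, 1 lower), the other 9 of -0.30 (2 higher, 6 lower). Permutation p was 0.093 (two-sided, 100000 resamples), leaving sharing open. FOXA2 (-1), in the 9, is on the floor plate list below.

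Cell cycle genes were lower in the bioreactor (limma's camera adjusted p = 0.0857 with an estimated correlation, so the call was lost). Undifferentiated iPSC left in adherent libraries are argued against as the source. The median of POU5F1, NANOG, TDGF1, PRDM14, ZSCAN10 and VRTN stood at 0.213% of its iPSC level there (0.14% to 0.541%), and the median cell cycle gene at 36.1%. All of these 6 factors but PRDM14 were among the 8 largest falls from iPSC. Over the whole pluripotency list the median log2 fold change was -5.01, against -1.47 for cell cycle genes. SOX2 fell less, to 185.7 ± 2.79 against 383.5 ± 8.3 CPM in iPSC. Scaling stays open: other scalings (cell cycle median -4.08 or lower) shift genes by up to -0.08.

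For each comparison, 1 of the 10 splits of its 6 libraries, the real one, gave as many called genes: 13144 for bioreactor against adherent, 13152 for adherent against iPSC and 13927 for bioreactor against iPSC, while the highest of the other splits was 0. The splits are too few for a share under 0.05.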

How the results depend on the processing

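No call for a named gene turned direction in any alternative, and most of 556 named gene results kept direction and side of the threshold. Of 123 list results, 59 lost their call with an estimated correlation, and with fry 42 gained one and 6 turned direction. The test against 1.5-fold gave 3798 higher and 4018 lower genes for bioreactor against adherent and 4228 and 3480 for adherent against iPSC, by construction fewer. With an estimated correlation, camera called 1 list higher and 7 lower for bioreactor against adherent, 4 and 1 for adherent against iPSC, and 0 and 0 for bioreactor against iPSC; fry called 30 lists higher for adherent against iPSC and 25 lower for bioreactor against iPSC. AFP, not called in bioreactor against iPSC, had -0.504 with a replicate block and -0.538 to 0.755 when 1 library was left out. The following are adjusted p of lists whose direction turned. With fry, they were 0.0154 for alpha cell markers and 0.688 for endocrine progenitor genes (bioreactor against adherent), 0.713 and 0.000506 for mesendoderm genes (adherent and bioreactor against iPSC), and 1.92e-05 for YAP targets and 3.14e-08 for hypoxia genes (bioreactor against iPSC). With a replicate block, they were 0.705 for endothelial markers (bioreactor against adherent), 0.909 for stomach genes and 0.951 for mesenchymal markers (bioreactor against iPSC), the last also at 0.886 with library totals. Leaving out 1 library gave 0.656 to 0.997 for endothelial markers, 0.679 to 0.984 for mitochondrially encoded genes, 0.908 to 0.969 for stomach genes and 0.896 to 0.998 for mesenchymal markers. None of these lists was called in the analysis reported, and the cause was not tested. Replicate numbers did not pair libraries: deviations from the group means had a mean r of 0.018 between same-numbered libraries and -0.006 between others. UCN3 had too few counts to test, and whether from depth or lack of expression was not tested.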

Other observations

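The lists in this part were chosen after seeing the data, and members whose values had been seen by then were left out of the counts and tests. Genes of motile cilia were higher in the bioreactor than in adherent libraries: 16 of 18 tested members rose and 2 fell (median log2 fold change 2.45, limma's camera adjusted p = 0.00011, adjusted p = 0.0208 with an estimated correlation). The ciliogenesis regulator FOXJ1 stood at 408 ± 38.5 against 76.9 ± 4.38 CPM, DNAH9, a dynein of cilia, at 61.8 ± 1.3 against 5.31 ± 0.88 CPM, and SPAG6 at 79.8 ± 4.22 against 14.1 ± 0.682 CPM. Of stratified epithelium and urothelium genes, 8 of 9 tested members fell and 1 did not pass (median log2 fold change -6.13, limma's camera adjusted p = 0.00326, adjusted p = 0.0449 with an estimated correlation). Of trophoblast and amnion genes, 1 of 9 tested members rose and 8 fell (median log2 fold change -3.63, limma's camera adjusted p = 0.0069, adjusted p = 0.0521 with an estimated correlation), with GATA3 at 0.577 ± 0.244 against 18.8 ± 0.783 CPM.

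For glutamate receptors, all 19 tested members rose (median log2 fold change 2.89, limma's camera adjusted p = 8.69e-07, adjusted p = 0.0208 with an estimated correlation), with GRIN3A at 91.3 ± 4.7 against 1.85 ± 0.531 CPM. For inhibitory transmission, 17 of 19 tested members rose, 1 fell and 1 did not pass (median log2 fold change 2.69, limma's camera adjusted p = 9.99e-05, adjusted p = 0.0208 with an estimated correlation). Of floor plate genes, which mark the ventral midline of the neural tube, 9 of 10 tested members rose and 1 fell (median log2 fold change 2.18, limma's camera adjusted p = 0.0022, adjusted p = 0.183 with an estimated correlation), with SPON1 at 878 ± 34 against 17.4 ± 0.158 CPM and NTN1 at 2052 ± 134 against 320.2 ± 15.2 CPM. Another 5 lists were not called, and 2 (forebrain and islet-restricted genes) had too few members left to test. For spinal cord and hindbrain interneuron transcription factors, 8 of 16 tested members rose, 6 fell and 2 did not pass (median log2 fold change 0.48, limma's camera adjusted p = 0.697). For motor neuron genes, 3 of 8 tested members rose, 4 fell and 1 did not pass (median log2 fold change -0.49, limma's camera adjusted p = 0.605). For serotonergic neuron genes, 5 of 8 tested members rose and 3 fell (median log2 fold change 0.60, limma's camera adjusted p = 0.451). For glial genes, 5 of 12 tested members rose, 4 fell and 3 did not pass (median log2 fold change 0.22, limma's camera adjusted p = 0.944). For thyroid and lung genes, 3 of 5 tested members rose and 2 did not pass (median log2 fold change 1.28, limma's camera adjusted p = 0.303).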
